A study of Homo sapiens with 12 samples.

How the data were processed

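Total RNA of 12 SH-SY5Y cultures was sequenced as stranded, ribosomal RNA-depleted libraries, per the labels' protocols. The deposited table lists 2 values for each of 19465 Ensembl gene IDs and each library. The first is TPM, which per the file headers is an estimate per gene. The second, per the file headers, is scaled reads per base, a signal on which the authors divided estimated reads by a size factor per library. Trimmomatic 0.35, FastQC 0.11.4, kallisto 0.42.4, sleuth 0.30.0 and the build hg19 are named, per the submitters' processing notes, without their order. The transcript index, and any filter that chose the genes listed, are not given in the sources used here. Kallisto assigns reads to transcripts by pseudoalignment, so reads that fit several near-identical transcripts are divided by estimation. 312 IDs had values equal to those of another ID in every library, and values of paralogs, pseudogenes and overlapping genes are uncertain for this reason.

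Symbols were taken by gene ID, and 18913 IDs matched one. In the GENCODE 29 annotation of GRCh38, 18982 IDs were present and 483 were not. Some IDs are newer than the hg19 build named, so no genome coordinates are given. The most abundant features included genes such as WDR74 and GOLGA2. The listed TPM of a library summed to 81.2% to 95.3% of the full total, and the rest lies in features not used here.

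Estimated counts had been assumed when the tests were planned. The values were not counts, so the test fixed for that case was used. Values were transformed as log2(TPM + 1), genes with at least 1 TPM in at least 3 libraries were kept (18270), and limma 3.58.1 in R 4.3.3 was fitted with a mean-variance trend to all 12 libraries, with 4 group means and 8 residual degrees of freedom. Contrasts were Synucleozid against DMSO, SNCA siRNA against scramble siRNA, the difference of these effects, and scramble siRNA against DMSO. P-values are two-sided and were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Fold changes on the log2(TPM + 1) scale understate the change of low genes. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1 and was not used.

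Depth was estimated from the scaled values. In each library the step that made the most values under 25 whole multiples, within 0.01 of a whole number, was taken as 1 fragment. 24.3% to 26.8% of such values were then whole, where chance gives 2%, so whole reads were not recovered and no negative binomial count model was fitted. Limma-voom, which takes values that are not whole, was run on the values divided by that step as an added alternative. The scaled sums divided by that step gave 5.97e+06 to 8.44e+06 fragments per library. These totals are estimates. No 2 libraries held equal values.

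Before the data were examined, 32 gene lists were fixed, and 650 of their 716 entries matched a listed gene by symbol or synonym. The 30 lists with at least 3 measured genes were tested with camera (preset inter-gene correlation 0.01), again with an estimated correlation, and with fry, which tests whether a list moves on balance in 1 direction and not whether it differs from other genes. The list of synucleins had 2 measured members and that of nuclear-retained noncoding RNAs had 0, so neither was tested as a list. The genes named were fixed by rule: up to 8 with the largest change per direction among genes past the threshold whose groups did not overlap and whose higher group averaged at least 50 scaled reads, the 8 smallest p-values, the synucleins, and of each list up to 3 members past the threshold or the member with the smallest p. HMGCS1, DHCR24, IDI1 and COL3A1 with Synucleozid, FTL and FTH1 there, and PCNA, MCM6 and GINS2 with siRNA were added as examples of their lists after their values were seen.

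The gene tests and list tests were tried on simulated data made from the real gene means and spreads over 18270 genes, with 200 genes changed per comparison in each of 5 simulations. For Synucleozid against DMSO, 38.5% of genes changed by 1.5-fold, 55.2% of those changed by 2-fold and 86.1% of those changed by 4-fold were called. For SNCA siRNA against scramble siRNA the shares were 38.5%, 60.9% and 86.7%. Of the calls, 5.26% and 4.62% were false in these comparisons. A list of 25 genes raised by 0.3 was called in 5 of 5 simulations of the first comparison, where 1 list that had not been changed was also called. No list was raised in the second comparison, and 0 were called there. Noise was drawn for each gene on its own, so the simulated lists had no inter-gene correlation. These runs therefore do not show how often camera calls correlated lists falsely. Among genes with a mean of at least 50 scaled reads, 75.7% and 85.2% of the 2-fold changes were called in the 2 comparisons. With 200 genes changed, the Benjamini-Hochberg cutoff is looser than in the real data, where 3 and 7 genes passed. The shares recovered therefore overstate what the tests could find in the real data.

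Alternatives covered the pseudocount, the filter on low values, the libraries in the fit, replicate numbers as a block, the threshold, leaving out each library and the set test. Rescaling of TPM, the scaled reads per base, limma-voom on depth-restored reads, a mean of at least 50 scaled reads, the GENCODE 29 primary annotation and leaving out the library with the lowest TPM sum in each arm were added after the data were seen. For the scan of short sequence words, the 3′ untranslated region of the transcript with the longest coding sequence was taken from GENCODE 29 for 14149 tested genes. The moderated statistic of each gene was adjusted for the length and base composition of that region and for mean expression, and genes with and without each of 15843 words of 7 bases, present in at least 100 genes, were compared by a z value. The scan ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. In simulated data a planted word, which lowered the statistic of its genes by 0.25, was ranked lowest in 18 of 20 runs. The rarest words scanned were not planted, and noise was drawn for each gene on its own. These runs therefore do not show how often correlated genes bring a word to the lowest rank falsely.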

Results

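The study asked how selectively Synucleozid acts on the transcriptome of a neuronal cell line. Synucleozid is a small molecule directed at the structured 5′ untranslated region of the SNCA mRNA, which encodes α-synuclein, the main protein of Lewy bodies, and it is meant to inhibit translation of that mRNA. The cells were SH-SY5Y, a human neuroblastoma line of sympathetic neuronal character that is widely used as a model of dopaminergic neurons. RNA from 12 cultures was sequenced after ribosomal RNA depletion, with 3 cultures in each of 4 groups, and all cultures were treated for 48 h. A compound arm held cells given the vehicle DMSO or Synucleozid, whose concentration is not given in the labels. An siRNA arm held cells given 0.1 µM of a pool of siRNAs against SNCA or of a scrambled siRNA. The labels call the replicates biological.

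The values were TPM for 19465 genes per library, of which 18270 reached 1 TPM in at least 3 libraries and were tested. Estimated depth was 7.67e+06 to 8.44e+06 fragments per library in the compound arm and 5.97e+06 to 6.55e+06 in the siRNA arm. The listed genes summed to between 81.2% of the full TPM total, in SNCA siRNA replicate 3, and 95.3%, in Synucleozid replicate 3. DMSO replicate 3 had the lowest sum of the compound arm, at 84.7%. Fold changes are log2 fold changes ± SE on the log2(TPM + 1) scale, from limma-trend over the 12 libraries with Benjamini-Hochberg adjustment.

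SNCA mRNA (ENSG00000145335), the target of both treatments, was measured first. It stood at 8.13 ± 1.90 TPM (SD, n = 3) with the SNCA siRNA pool and at 16.1 ± 1.40 TPM (SD, n = 3) with the scrambled siRNA, a level 49.6% lower. The log2 fold change was -0.93 ± 0.16, with a limma 95% interval from -1.28 to -0.58, and all 3 SNCA siRNA libraries lay below all 3 scramble libraries. Its adjusted p was 1.7e-04 over the 2 synuclein genes measured, adjusted over the list alone, but 0.098 over all genes tested, which missed the threshold of 0.05. With Synucleozid, SNCA mRNA stood at 15.9 ± 1.21 TPM (SD, n = 3) against 14.5 ± 2.49 TPM (SD, n = 3) in DMSO. That log2 fold change was 0.13 ± 0.16 (limma adjusted p = 0.97), with a 95% interval from -0.22 to 0.49, so that a fall below 0.86 of the DMSO level or a rise above 1.40 times it lay outside the interval. The effects of the 2 treatments on SNCA mRNA differed by 1.06 ± 0.23 (limma adjusted p = 0.0011 over the synucleins alone and 0.38 over all genes). SNCB, encoding β-synuclein, was near the detection limit in every group, with means of 1.87 to 3.13 TPM, and did not pass in either comparison.

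**Figure D1:**
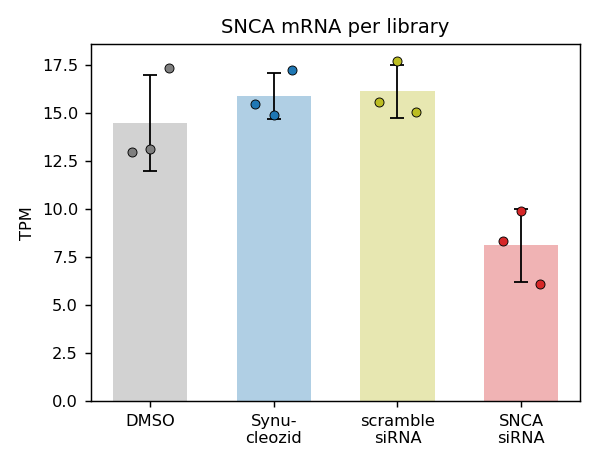
SNCA mRNA in TPM (vertical axis, linear, from 0) in the 4 groups (horizontal axis). Points are single libraries, bars are group means and error bars are SDs over 3 libraries; the SNCA siRNA mean is 8.13 TPM, against 14.5 to 16.1 TPM in the other groups.

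Few mRNAs separated Synucleozid from DMSO. IGFBP5 (ENSG00000115461), a secreted insulin-like growth factor binding protein, fell from 121 ± 13.1 to 66.9 ± 2.40 TPM (SD, n = 3 each), a log2 fold change of -0.84 ± 0.08 (limma adjusted p = 0.0016). Its relative IGFBP3 (ENSG00000146674) fell from 57.1 ± 6.29 to 27.7 ± 2.05 TPM, by 1.01 ± 0.11 on the log2 scale (adjusted p = 0.0059). THSD7A (ENSG00000005108), a thrombospondin-type membrane protein, rose from 43.5 ± 1.72 to 63.6 ± 2.55 TPM, a log2 fold change of 0.54 ± 0.06 (adjusted p = 0.011). These 3 were the only genes past the threshold of the 18270 tested. Next in rank, and not past it, were LGR5, a receptor for R-spondins (log2 fold change 0.44 ± 0.06, adjusted p = 0.054), the intermediate filament VIM (-0.69 ± 0.10, adjusted p = 0.059), FAM107B (-0.51 ± 0.08, adjusted p = 0.059), the sterol carrier STARD4 (0.60 ± 0.09, adjusted p = 0.081) and the extracellular matrix gene TNR (0.60 ± 0.10, adjusted p = 0.15). At an unadjusted p under 0.05, 560 genes lay higher and 502 lower, against 913.5 expected by chance in all. The same genes had levels in the scramble siRNA libraries, which received no compound, close to those with Synucleozid: 67.1 ± 1.82 TPM for IGFBP5, 30.1 ± 1.43 for IGFBP3, 66.4 ± 3.52 for THSD7A and 163 ± 8.49 for VIM, against 281 ± 37.8 for VIM in DMSO and 174 ± 11.0 with Synucleozid. Only IGFBP5 passed whichever single library of the compound arm was left out: without DMSO replicate 1, DMSO replicate 2 or Synucleozid replicate 1 it was the 1 call that remained. Limma-voom on depth-restored reads called 18 genes, among them these 3, and no gene passed a test against a change of 1.5-fold.

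**Figure D2:**
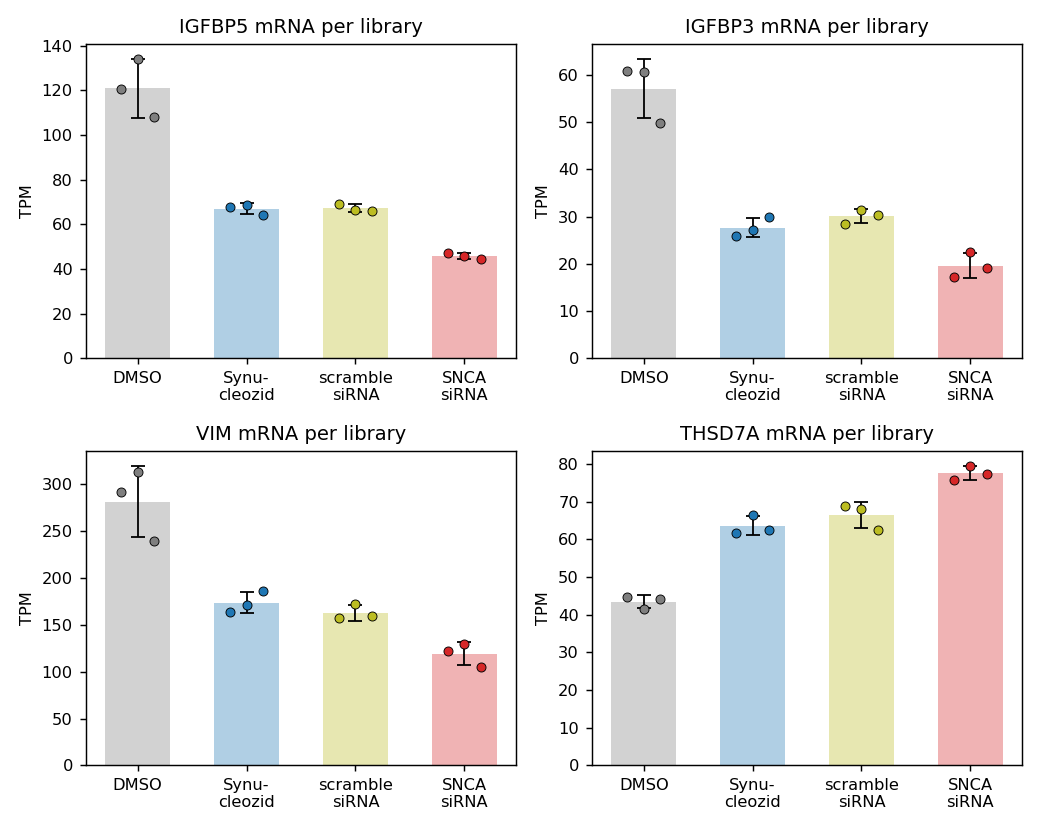
TPM (vertical axes, linear, from 0) of IGFBP5, IGFBP3, VIM and THSD7A in the 4 groups (horizontal axes). Points are libraries, bars group means and error bars SDs over 3 libraries; for IGFBP5 the DMSO mean is 121 TPM, against 66.9 with Synucleozid, 67.1 with scramble siRNA and 45.7 with SNCA siRNA.

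Among the gene lists fixed before the data were examined, genes of cholesterol biosynthesis and markers of the mesenchymal, substrate-adherent (S-type) state of neuroblastoma cells were the 2 called by fry with Synucleozid, and S-type markers were the only list called by camera with an estimated correlation. All 24 measured cholesterol genes had positive log2 fold changes, with a median of 0.25, and the list was higher by camera (adjusted p = 7.5e-16). Its adjusted p was 0.051 with an estimated correlation and 0.012 by fry. None passed over all genes, but 10 passed adjusted over the list alone, among them STARD4, HMGCS1 (0.44 ± 0.08), which makes the precursor of mevalonate, DHCR24 (0.33 ± 0.07), which acts at the last steps of the pathway, and the isomerase IDI1 (0.39 ± 0.09). S-type markers were lower in 18 of 21 measured genes, with a median of -0.13 (camera adjusted p = 2.0e-06, or 0.015 with an estimated correlation). IGFBP5 passed over all genes, and IGFBP5, VIM and the collagen COL3A1 (-0.71 ± 0.18) passed adjusted over the list alone. In the scramble siRNA libraries the medians against DMSO were 0.28 for cholesterol genes and -0.25 for S-type markers.

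Further lists passed camera in the same comparison, the first 6 with adjusted p of 1.8e-08 to 6.7e-05 and the other 8 with 8.1e-04 to 0.018, but all 14 calls were lost with an estimated correlation. For Schwann-type markers and interferon genes that estimate (-0.02 and 0.005) lay below the preset 0.01. A higher correlation within those lists thus did not remove their calls. Higher by camera with the preset correlation, though not with an estimated one (0.23 to 0.59), were immediate early genes (17 of 18 with positive values, median 0.28, led by FOS at 1.16 ± 0.24), p53 targets (23 of 24, median 0.19, led by MDM2 at 0.25 ± 0.09), genes of axons and the neuronal cytoskeleton (20 of 24, median 0.18, led by GAP43 at 0.45 ± 0.10) and cytosolic ribosomal proteins (50 of 50, median 0.09). Genes of G2/M and mitosis (21 of 24 with negative values, median -0.13, led by NUSAP1 at -0.21 ± 0.07) and of S phase and replication (23 of 25, median -0.10, led by E2F1 at -0.26 ± 0.09) were lower by the same test, with adjusted p of 0.34 and 0.43 with an estimated correlation. No member of these 6 lists passed over all genes. In the scramble siRNA libraries, which received no compound, the medians against DMSO were 0.20 for immediate early genes and 0.18 for p53 targets. They were 0.15 for axon genes, 0.04 for ribosomal proteins, -0.09 for G2/M and -0.06 for S phase. FOS was near the detection limit, with means of 1.43 TPM in DMSO, 4.29 with Synucleozid and 3.43 with scramble siRNA. Catecholaminergic neuron markers (median 0.09), synaptic vesicle genes (0.08), Parkinson disease genes (0.09), nuclear respiratory chain subunits (0.08), mitochondrially encoded mRNAs (0.11) and the unfolded protein response (0.13) were also called higher, and Schwann-type and glial markers (-0.25) and type I interferon genes (-0.08) lower, with adjusted p of 0.17 to 0.59 with an estimated correlation. With scramble siRNA against DMSO the medians of these 8 lists, in the same order, were 0.03, 0.02, 0.10, 0.11, 0.09, 0.13, -0.04 and -0.05. Among catecholaminergic markers the proneural factor ASCL1 went the other way, at 10.1 ± 1.66 TPM in DMSO, 5.42 ± 0.06 with Synucleozid and 5.43 ± 0.48 with scramble siRNA (SD, n = 3 each; log2 fold change with Synucleozid -0.78 ± 0.15, limma adjusted p = 0.18). Other mRNAs that carry an iron-responsive element, the kind of hairpin named for the SNCA 5′ untranslated region, were not called as a group: 6 of 10 had positive values, the median was 0.03 and camera's adjusted p was 0.47, with SLC40A1 (ferroportin) at 0.39 ± 0.21, FTL at 0.13 ± 0.09 and FTH1 at 0.04 ± 0.08. The compound is meant to inhibit translation, which mRNA levels do not measure. These values therefore cannot show whether translation of those mRNAs was affected. The remaining 13 lists, among them iron handling, autophagy, the integrated stress response, NRF2 targets and heat shock genes, were not called, with adjusted p of 0.13 to 0.92. DMSO replicate 3 lay apart from its group on the first principal component (1.19, against -17.1 and -13.2), and without it the number of lists called fell from 16 to 7. Cholesterol genes, S-type markers, axon genes, immediate early genes, p53 targets, G2/M and S phase kept their calls with the preset correlation, and the other 9 lost theirs. Without Synucleozid replicate 3, ribosomal proteins (adjusted p = 0.29), mitochondrially encoded mRNAs (0.79), respiratory chain subunits (0.26) and interferon genes (0.073) lost theirs. The mitochondrial and ribosomal lists thus rested on these 2 libraries, which had the lowest and highest TPM sums of the arm: RPL38 stood at 1295 and 1321 TPM in Synucleozid replicates 1 and 2, within the DMSO range of 1105 to 1391 TPM, and at 1653 TPM in replicate 3. The mitochondrial list was also not called in a fit to the 6 libraries alone (adjusted p = 0.075).

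Reduction of SNCA by siRNA went with lower mRNA of 7 genes and higher mRNA of 0 at the threshold, by limma-trend. CTCF (ENSG00000102974), the chromatin insulator protein, fell from 46.9 ± 0.56 to 30.0 ± 0.97 TPM (SD, n = 3 each), a log2 fold change of -0.63 ± 0.07 (adjusted p = 0.0092). SYNJ2BP, a mitochondrial outer membrane protein, fell from 46.9 ± 2.65 to 31.4 ± 0.83 TPM, EIF1AX, a translation initiation factor, from 100 ± 4.99 to 71.5 ± 2.49 TPM, and API5, an inhibitor of apoptosis, from 100 ± 9.20 to 66.9 ± 2.09 TPM. CREB5, a transcription factor of the CREB family, had the largest change, from 29.5 ± 6.43 to 13.0 ± 2.87 TPM (-1.12 ± 0.16), beside 17.5 ± 0.92 TPM in DMSO. PSAT1, an enzyme of serine synthesis, fell from 77.4 ± 1.88 to 51.1 ± 6.09 TPM, and IGFBP5 from 67.1 ± 1.82 to 45.7 ± 1.36 TPM (-0.54 ± 0.08). Means in DMSO were 45.8 TPM for CTCF, 43.7 for SYNJ2BP, 88.5 for EIF1AX, 85.9 for API5, 72.1 for PSAT1 and 121 for IGFBP5. Scramble siRNA thus stood above DMSO for genes such as EIF1AX and API5, and SNCA siRNA stood below DMSO for all 7. The adjusted p of each of the 6 genes other than CTCF was 0.040. RRM2, a ribonucleotide reductase subunit, came next (-0.48 ± 0.07, adjusted p = 0.065), and the glycolytic enzyme PGAM1 lay close behind (-0.49 ± 0.08, adjusted p = 0.075). At an unadjusted p under 0.05, 729 genes lay higher and 1100 lower, against 913.5 expected by chance in all. The calls depended on the fit: the 6 siRNA-arm libraries alone, with fewer residual degrees of freedom, gave 0 genes, as did the replicate block over all 12 libraries. The compound-arm libraries alone, with as few degrees of freedom, kept 2 of the 3 Synucleozid calls. Libraries of the siRNA arm correlated less with their own group (0.976 to 0.982, against 0.983 to 0.986 in the compound arm). The fit to all 12 libraries shares 1 spread per gene, so it may understate the spread in the siRNA arm. Limma-voom on depth-restored reads of all 12 called 12 genes, with IGFBP5 no longer among them. Leaving out SNCA siRNA replicate 1, SNCA siRNA replicate 3 or scramble siRNA replicate 3 also left 0 calls, leaving out SNCA siRNA replicate 2 kept 3 of the 7, and leaving out scramble siRNA replicate 1 or 2 kept 1 of the 7, CTCF, and added 1 other gene each time.

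**Figure D3:**
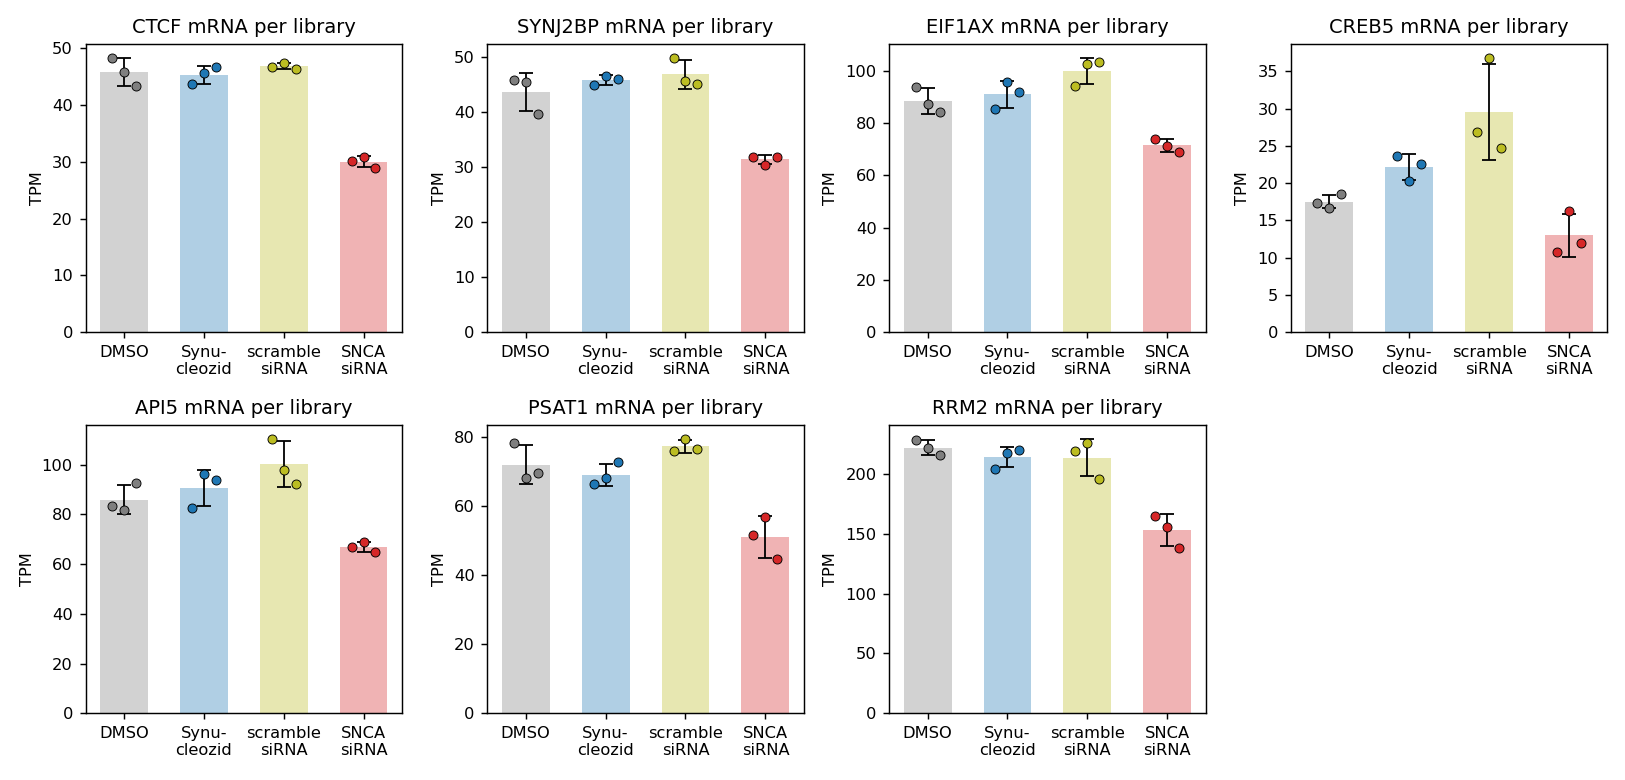
TPM (vertical axes, linear, from 0) of CTCF, SYNJ2BP, EIF1AX, CREB5, API5, PSAT1 and RRM2 in the 4 groups (horizontal axes). Points are libraries, bars group means and error bars SDs over 3 libraries; CTCF averages 30.0 TPM with SNCA siRNA and 46.9 TPM with scramble siRNA, and RRM2, which missed the threshold, is shown beside the called genes.

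Genes of S phase and mitosis were lower as lists with the SNCA siRNA pool by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.25 and 0.46). All 25 measured genes of S phase and replication had negative log2 fold changes, with a median of -0.25 (camera adjusted p = 1.4e-15, or 0.25 with an estimated correlation and 0.031 by fry). None passed over all genes and 14 passed adjusted over the list alone, among them RRM2, the sliding clamp PCNA (-0.40 ± 0.08), the replicative helicase subunit MCM6 (-0.36 ± 0.08) and the GINS subunit GINS2 (-0.60 ± 0.12). All 24 genes of G2/M and mitosis were also negative, with a median of -0.18, led by HMMR (-0.38 ± 0.08), and 1 passed adjusted over the list alone (camera adjusted p = 4.4e-09, or 0.46 with an estimated correlation). Replication-dependent histones were negative in 19 of 19 (median -0.30), ribosomal proteins in 49 of 50 (median -0.14) and genes of the integrated stress response in 22 of 25 (median -0.18), the last led by PSAT1. With an estimated correlation the adjusted p of these 3 lists was 0.54 to 0.63. SNCA siRNA replicate 3, the library with the lowest TPM sum, lay apart from its group on the first principal component (33.5, against 9.19 and 17.3) and had the lowest RRM2 of the group (138 TPM, against 156 and 164), though not the lowest HMMR. Scramble siRNA replicate 3 also lay apart from its group on that component (-14.0, against 3.88 and 15.4). Without SNCA siRNA replicate 3 the median was -0.18 for S phase, -0.12 for G2/M and -0.15 for histones, all still called by camera with the preset correlation, and the ribosomal list was no longer called (adjusted p = 0.070). Without scramble siRNA replicate 3 the medians were -0.25, -0.22 and -0.24, and these lists and the ribosomal list (-0.18) were called with the preset correlation.

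S-type markers were lower in 15 of 21 (median -0.17, camera adjusted p = 0.018, or 0.25 with an estimated correlation and 0.031 by fry). The other lists called lower by camera were hypoxia and glycolysis, nuclear respiratory chain subunits, the unfolded protein response, translation factors, NRF2 targets and heat shock genes, with medians of -0.15 to -0.08 and adjusted p of 0.46 to 0.63 with an estimated correlation. No list was called higher. Cholesterol genes, at a median of -0.11, were not called (adjusted p = 0.055), nor were Parkinson disease genes (-0.03, 0.70), type I interferon genes (0.08, 0.42), the RNA interference machinery (-0.02, 0.95) or mRNAs with an iron-responsive element (-0.05, 0.34). The 13 further lists had adjusted p of 0.055 to 0.95.

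The effects of Synucleozid and of the SNCA siRNA pool were then compared with each other. IGFBP5 was the 1 gene past the threshold in both, lower in each, where independent lists of these sizes would share 0.00077 genes (Fisher's exact p = 7.7e-04, two-sided). Both values assume independent calls, but the 2 comparisons used the same spread estimate per gene, so they are not a chance level for the overlap. That overlap was lost when any Synucleozid library, any siRNA-arm library or DMSO replicate 1 was left out, and with limma-voom, where the 2 shared genes were KCTD12 and GREM2 (named after their values were seen). At an unadjusted p under 0.05, 50 genes lay higher in both against 22.3 expected, and 68 lay lower in both against 30.2 expected, while 39 and 30 went in opposite directions against 33.7 and 20.0 expected. These expected counts assume independence too, and the opposite directions also lay above them. Across all 18270 genes, which are not independent replicates, the log2 fold changes of the 2 comparisons were not correlated in a common direction (Pearson's r = -0.03, Spearman's rho = -0.04). No gene's effect differed between the treatments past the threshold by limma-trend, limma-voom on depth-restored reads or any other setting run. At an unadjusted p under 0.05 there were 1485 such genes by limma-trend, against 913.5 expected by chance. Cholesterol genes differed most (23 of 24 higher with Synucleozid relative to siRNA, median difference 0.35, camera adjusted p = 2.8e-11). That list's adjusted p was 0.25 with an estimated correlation and 0.037 by fry.

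The vehicle and the scrambled siRNA, the controls of the 2 arms, differed in 9 genes by limma-trend. THSD7A (0.60 ± 0.06), HMGCS1 (0.56 ± 0.08) and LGR5 (0.41 ± 0.06) were higher with scramble siRNA, and IGFBP5 (-0.83 ± 0.08), IGFBP3 (-0.90 ± 0.11), VIM (-0.78 ± 0.10), the calponin CNN2 (-0.54 ± 0.08) and the tetraspanin TSPAN18 (-0.49 ± 0.07) were lower, with adjusted p of 8.7e-04 to 0.047. The ninth was RPS28P7, a processed copy of the ribosomal protein gene RPS28, which was listed at or near 0 in all 6 compound-arm libraries and at 153 to 532 TPM in the 6 siRNA-arm libraries. In this comparison cholesterol genes (median 0.28, 14 of 24 passing adjusted over the list alone) were higher and S-type markers (median -0.25) and histones (19 of 19 negative, median -0.32) lower by camera, and with an estimated correlation only the S-type list kept its call (adjusted p = 0.033, against 0.11 for cholesterol genes and 0.75 for histones). A fit to these 6 libraries alone called 1 gene, RPS28P7, and 3 genes remained without DMSO replicate 1 or DMSO replicate 2. Transfection, arm and any sequencing run that differed between the arms could not be told apart in this comparison.

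**Figure D4:**
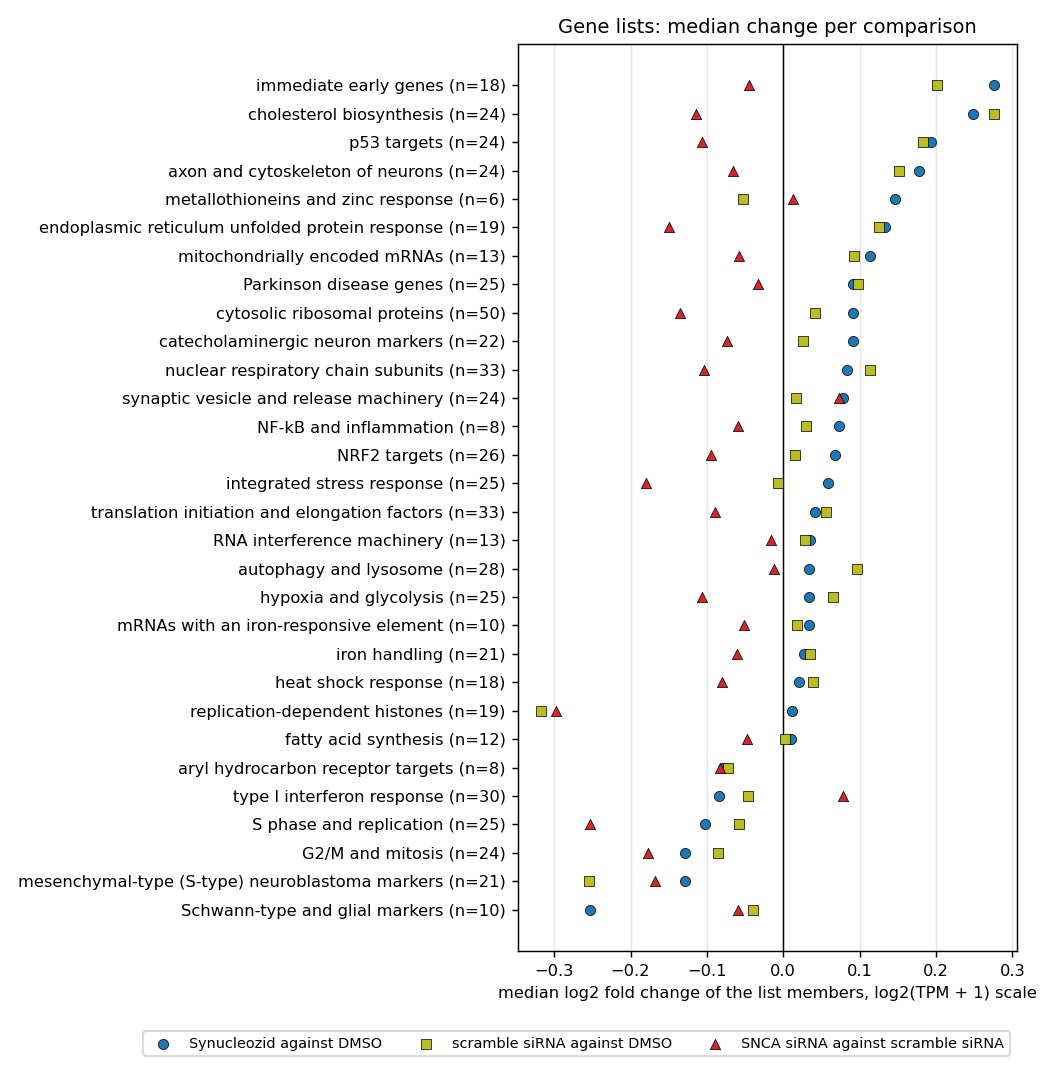
Median log2 fold change (horizontal axis, log2(TPM + 1) scale) of the measured members of each of 30 gene lists (vertical axis, with the number of genes measured). Circles are Synucleozid against DMSO, squares scramble siRNA against DMSO and triangles SNCA siRNA against scramble siRNA; cholesterol genes lie at 0.25, 0.28 and -0.11 in that order, and S phase genes at -0.10, -0.06 and -0.25.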

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

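The test of the difference was planned, and the bounds for the other splits were written after the split results had been seen. SNCA was taken for a closer look because the 2 treatments differed in their effect on it by a test of the difference itself. The effect of Synucleozid minus that of the SNCA siRNA pool was 1.06 on the log2 scale (SE 0.23, limma adjusted p = 0.0011 over the 2 synucleins measured and 0.38 over all genes). SNCA mRNA was lower in 3 of 3 SNCA siRNA libraries than in any scramble siRNA library, whereas the Synucleozid libraries, at 14.9 to 17.3 TPM, lay within the range of the DMSO libraries, at 13.0 to 17.4 TPM. Groups of 3 were not tested for outlying libraries.

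Other splits of the same libraries were refitted for every count. Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. Synucleozid against DMSO gave 3 genes, and the highest of the other splits gave 1. SNCA siRNA against scramble siRNA gave 7 genes, against 2 in the highest other split, and scramble siRNA against DMSO gave 9, against 1. In each of these only the real split, 1 of 10, reached its own count. For gene lists called by camera with the preset correlation, the real counts of 16, 12 and 13 stood beside 14, 11 and 12 in the highest other split of the same comparisons, and again 1 split of 10 reached each. For the difference of effects, 100 splits were drawn: the real one gave 0 genes, which all 100 reach by definition, so this count decides nothing (7 in the highest). The 16 lists called there were reached in 3 of the 100 splits, with 16 in the highest other. That share lies under 0.05, but this bound was written after the splits were seen, and other splits tied with the real one. The splits relabel libraries in both arms, so a small share does not show that the 2 effects differ. With an estimated correlation, 0 of those lists kept their call.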

How the results depend on the processing

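Rescalings of TPM, scaled reads per base, limma-voom on depth-restored reads, the filter on 50 scaled reads, the restriction to the primary annotation and the omission of DMSO replicate 3 with SNCA siRNA replicate 3 were added after the data were seen. SNCA kept its direction and its side of the threshold in both comparisons and in their difference under every alternative run, and the difference of effects gave 0 genes under each. Genes called were 3 for Synucleozid, 7 for SNCA siRNA, 9 between the controls and 1 shared. With scaled reads per base these became 14 (4 higher, 10 lower), 14, 16 (5 higher, 11 lower) and 2, and with limma-voom 18 (4 higher, 14 lower), 12, 16 (5 higher, 11 lower) and 2. With a mean of at least 50 scaled reads they became 7, 11 and 16. Median ratios and upper quartiles each gave 5 for Synucleozid. The 1.5-fold test gave 0, 0, 1 and 0 shared. BH 0.01 gave 1 for SNCA siRNA, 3 between the controls and 0 shared. Only the 6 libraries of a comparison, with fewer residual degrees of freedom, gave 2 for Synucleozid, 0 for SNCA siRNA, 1 between the controls and 0 shared. Without the lowest-sum library of each arm, SNCA siRNA had 3 calls (2 higher, 1 lower), of which 1 was among the 7, and 0 were shared. The cause of these changes was not tested.

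Gene lists called were 16 for Synucleozid and 12 for SNCA siRNA. An estimated correlation gave 1 and 0, fry gave 2 and 2, and the omission of the lowest-sum libraries gave 8 for Synucleozid. Leaving out single libraries gave 1 to 4 genes for Synucleozid, 0 to 3 for SNCA siRNA, 3 to 6 between the controls, 0 to 0 for the difference and 0 to 1 shared, 7 to 18 lists for Synucleozid and 8 to 12 for SNCA siRNA. SNCA ranged from 0.06 to 0.26 with Synucleozid, from -1.07 to -0.76 with siRNA and from 0.89 to 1.20 for the difference. With Synucleozid, SNCB (0.01) ranged from -0.0874 to 0.124 and FTH1 (0.04) from -0.0224 to 0.109, and FTH1 was -0.0224 without the lowest-sum libraries. Of 869 values of single named genes, 687 stayed on the same side of the threshold, 148 lost a call, 31 gained one and 3 changed sign.

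The replicate block gave 2 genes for Synucleozid, 0 for SNCA siRNA, 5 between the controls and 0 shared, and 16 and 12 lists. Deviations of same-numbered libraries correlated at -0.09, -0.03 and -0.12 in the compound arm and -0.07, 0.06 and -0.03 in the siRNA arm, so the numbers were not taken to pair samples. Not run, for want of counts, transcripts or effective lengths, were edgeR with other normalizations, DESeq2, voom on counts, filters on counts, a length offset and transcript-level tests.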

Other observations

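The test of the DMSO libraries was chosen after its result was seen, as were the read-based bound used for RPS28P7 and the separate test of CREB5, and the other tests were fixed before. The most abundant features over the 12 libraries were WDR74, with a mean of 14364 TPM (SD 2881 over the 12 libraries), the mitochondrial mRNA MT-CO1 (8436 TPM) and GOLGA2 (8227 TPM). WDR74 and GOLGA2 thus stood above EEF1A1 (5808 TPM) and ACTB (2807 TPM). Values of overlapping genes are uncertain here, so the WDR74 and GOLGA2 values may not be their mRNA levels. MAOA, which degrades monoamine transmitters, stood at 36.9 ± 3.20 TPM with SNCA siRNA and 28.8 ± 2.51 TPM with scramble siRNA (SD, n = 3 each; limma adjusted p = 0.31).

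The 3 genes called with Synucleozid may reflect DMSO libraries that stand apart rather than the compound. IGFBP5, IGFBP3 and THSD7A differed between Synucleozid and scramble siRNA by -0.00, -0.12 and -0.06 on the log2 scale (SE 0.08, 0.11 and 0.06), each under 0.5 of the difference from DMSO, and the largest of these in size was -0.12. Cholesterol genes and S-type markers had median differences of -0.02 and 0.02 between the same groups. Those of p53 targets, axon genes, the unfolded protein response, Parkinson disease genes and respiratory chain subunits were 0.02, 0.02, -0.04, -0.02 and -0.02. Immediate early genes (0.20), Schwann-type markers (-0.14), synaptic vesicle genes (0.09) and catecholaminergic markers (0.08), however, kept more than 0.5 of their shift from DMSO, and histones differed by 0.37. Across all genes the covariance of the 2 sets of changes from DMSO was 0.0244 (Pearson's r = 0.48). It was 0.0238 (r = 0.50) when simulated for unchanged groups sharing these 3 controls. The simulation gave every group the spread pooled over the 4 groups, so it cannot tell whether the departure was general. By limma-trend, 1 gene differed between Synucleozid and scramble siRNA past the threshold, beside 9 between the controls. That gene was RPS28P7, at 0 TPM with Synucleozid and a mean of 287 TPM with scramble siRNA, and it is also 1 of those 9. An effect of the compound that equals that of transfection stays open, since arm, transfection and any difference of run cannot be told apart here and the 3 DMSO libraries are too few to divide.

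Lower mRNAs with the SNCA siRNA pool may in part be targets of the siRNAs through short seed matches, a known property of siRNAs. Over 15843 words of 7 bases in 3′ untranslated regions, the word whose genes lay lowest was AAGCCTA (z = -5.26, 981 genes), below the lowest word of the 9 other splits (-4.81), although 10 splits cannot give a share under 0.05 and a split of the scramble siRNA and DMSO libraries reached -5.93. It occurs in SNCA mRNA, as do 20.1% of the words tested, and with the second lowest word, AGCCTAA, it forms AAGCCTAA, found in 11 of 13 SNCA transcripts. The shift was small: the mean log2 fold change was -0.0415 in 298 genes with the longer word and -0.0155 in 12554 genes with neither word. In 1297 genes with either 7-base word but not the longer one, that mean was -0.0195. Of the 7 called genes, 6 held neither word in the 1 region searched per gene, which had only 154 bases in API5. This argues against a match to this seed in those regions alone. Other transcripts of these genes, other siRNAs of the pool, whose sequences were not used here, and an effect of SNCA loss stay open. The other called gene, CREB5, held both words (0.789 expected to hold either, Fisher's exact p = 0.567). A match there stays open because 1.56 were expected at the same lengths.

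RPS28P7, at or near 0 in the compound arm and at 153 to 532 TPM in the siRNA arm, may hold reads of its parent gene RPS28 that were assigned differently. RPS28 stood at 302 TPM in the siRNA arm and 323 TPM in the compound arm, a ratio of 0.935, between the bounds written beforehand, which were also unsuited because TPM weights a short copy by its effective length. The transfer would need 149.8 scaled reads per library, below the SD of RPS28 within groups (437 scaled reads), so this explanation and a difference in RNA or library between the arms cannot be told apart. No biological explanation was tested.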
